A study of Mus musculus with 15 samples.

How the data were processed

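Poly(A)-enriched RNA of 15 mouse libraries was sequenced in 2 experiments. The labels give the cell type as MSCLCs, an abbreviation they do not spell out, and the series title names bone mesenchymal stem cells. Experiment 1 held 3 libraries of the genotype label MSC (title numbers 202, 234 and 237), called WT here since the titles of 234 and 237 add WT, and 4 of the genotype label EFPrx1MSCLC (title numbers 219, 221, 225 and 229), called EF here. Experiment 2 held 2 libraries of the genotype label EF, 2 of ha and 4 of hr, and every title of experiment 2 carries the number 221. The titles of hr add Combi and uns, those of ha Combi and T, and those of EF neither. The meaning of EF, ha and hr, and whether EF is the same genotype as EFPrx1MSCLC, is not given in the sources used here. No label states whether libraries of one group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. The experiments were run on different flowcells, which cannot be told apart from the experiment, so no test was made between them.

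The authors deposited a table of expected counts per gene, which are estimated read counts that need not be whole. Alignment with STAR, estimation with RSEM and the genome build GRCm38.p6 are named in the submitters' processing notes, without versions. The annotation release and whether counting used the strand are not given in the sources used here, so reads of a gene and an overlapping or antisense gene may not have been separated. RSEM divides reads between near-identical copies, so values of paralogs and pseudogenes are uncertain. The table held 55471 genes, of which 55144 had a symbol in the annotation and 55230 a position; positions are given on GRCm38. A symbol shared by several identifiers occurred 213 times, and each gene was followed by its identifier. The fusion EWS::FLI1 is not a feature of its own in the table, so the counts of the mouse genes Fli1 and Ewsr1 do not check the genotype labels.

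Expected counts were rounded to whole numbers; 8.27% of the deposited expected counts were not whole, and rounding changed no library total by more than 0.000579%. Genes with low counts were removed with edgeR's filterByExpr by group (minimum count 10), libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 7 libraries of experiment 1 were fitted together. The 8 libraries of experiment 2 were fitted together, so that EF, ha and hr share one estimate of the spread. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Errors of log2 fold changes are standard errors from the quasi-likelihood F statistic, and group levels are TMM-normalised CPM, mean ± SD. Values per library in the closing section are CPM of the library total where this is said.

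Genes named in the text follow a rule: 16 key genes in every comparison, the 8 genes of largest change in each direction with groups that do not overlap and a mean of at least 10 CPM in the higher group, and up to 4 called members of each gene list by p-value. Some genes that this rule selects are not reported here. The 21 gene lists were EWS::FLI1-activated and EWS::FLI1-repressed genes, YAP1/TAZ-TEAD targets, Hippo pathway components, the IGF axis, mesenchymal stromal markers, osteoblast, chondrocyte, adipocyte, proliferation and neural genes, EMT and contractile genes, interstitial collagens and matrix, interferon response, p53 and senescence, glycolysis and hypoxia, and markers of hematopoietic, endothelial, myogenic, epithelial and osteoclast cells. Both EWS::FLI1 lists hold genes reported in human Ewing sarcoma cells, and the YAP1/TAZ-TEAD list is a signature from pan-cancer studies. None of them was derived in mouse mesenchymal cells, so they do not directly measure fusion or YAP1 activity here. Lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists and comparisons together. Tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. Camera with an estimated correlation and fry were the alternatives for lists. The preset correlation assumes that members of a list vary almost independently between libraries. Of 70 list tests, 24 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.118. The estimated version also takes its degrees of freedom from the few libraries in place of the genes. Its p-values can thus be larger without any correlation between members. The strongest experiment 1 genes, up to 200 per direction, were tested as lists in experiment 2.

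Alternatives for the gene tests were DESeq2 size factors, no filter and a stricter filter (5 CPM), DESeq2's Wald test, limma-voom, a fold threshold, the number of the title as a block, fits of only the groups compared, hr libraries summed by the first number of their titles, and leaving out each library in turn. Added after the data were seen were the sum of library pairs that differed by little more than sampling noise, and counts restricted by chromosome or to genes expressed in experiment 2. Total counts ranged from 14906180 to 26833876 in experiment 1 and from 11195371 to 16378368 in experiment 2. A count of 0 allows up to 3 counts, or 0.112 to 0.268 CPM by library. Folds against a group at 0 are given as bounds from that floor per library. A ratio given as a range is a binomial confidence interval on counts summed over the libraries of each group. Intervals and floors cover counting error only, not the spread between libraries.

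The scripts were tested on simulated data with 200 changed genes drawn from the real means and library sizes. In a first run with only 2-fold and 4-fold changes edgeR recovered none of the 2-fold genes in EF against WT, and 16-fold genes were then added. In the simulation of EF against WT (14596 genes), edgeR recovered 0% of genes changed 2-fold, where DESeq2 recovered 13.3% and limma-voom 0%, 34% of those changed 4-fold and 81.3% of those changed 16-fold. In the simulation of ha against EF (13998 genes) it recovered 42.7%, 92% and 100%, for hr against EF 57.3%, 94% and 98.7%, and for hr against ha 52%, 96% and 100%.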

Results

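RNA-seq was available for 15 libraries of cultured mouse mesenchymal cells. The series title places them in a study of YAP1, a transcriptional coactivator held in check by the Hippo kinases, of EWS::FLI1, the fusion transcription factor of Ewing sarcoma, and of IGF-1, a growth factor. In experiment 1, 3 libraries of the genotype label MSC (WT, a word that 2 of their 3 titles add) and 4 of the label EFPrx1MSCLC (here EF) were sequenced to 14906180 to 26833876 counts each. In experiment 2, 2 libraries of the label EF, 2 of ha and 4 of hr, all with the title number 221, were sequenced to 11195371 to 16378368 counts each; what ha and hr stand for, and whether the label EF means the same as EFPrx1MSCLC, is not given in the sources used here. Titles of the ha libraries add Combi and T and those of the hr libraries Combi and uns, words that the labels do not explain, and EF titles add neither. Replicates differed in how far apart they lay. Distances are medians over genes of the squared difference between 2 libraries, relative to the median that sampling noise of counts alone gives. This ratio was 1.36 for the 2 EF libraries of experiment 2, and 1.32 and 1.31 for the hr libraries with the same first title number. It was 12.5 to 13.6 for the other hr pairs, 16.3 for the 2 ha libraries and 6.19 to 76.1 for pairs within the groups of experiment 1. The EF pair and the close hr pairs were kept as separate libraries in the main fits. A difference just above sampling noise does not show that they are separate samples, and they may be repeat libraries of the same sample. The p-values of experiment 2 count them as replicates and rest on this choice. Results that need it are named. Levels are TMM-normalised CPM, counts scaled to a common library total (mean ± SD), and changes are log2 fold changes ± standard error from edgeR, on the build GRCm38.

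Experiment 1 asked what differed between EF and wild-type cells. Saa3, an acute-phase protein gene, fell by 10.51 ± 0.55 on the log2 scale from 3557 ± 462 CPM in WT (n = 3) to 2.43 ± 1.12 CPM in EF (n = 4; edgeR adjusted p = 0.000289), and the neutrophil chemokine gene Cxcl5 fell by 10.48 ± 0.56 (edgeR adjusted p = 0.000289). Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator ARF (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), fell by 6.59 ± 1.19 from 89.5 ± 39.7 to 0.954 ± 1.02 CPM (edgeR adjusted p = 0.00998). Pgr, the progesterone receptor gene, rose by 8.75 ± 1.24 from 0.108 ± 0.0953 to 53.4 ± 48.5 CPM (edgeR adjusted p = 0.00463). Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596) rose by 1.09 ± 0.30 from 92.6 ± 37.5 to 197 ± 18.2 CPM, with all 4 EF libraries above all 3 WT libraries (edgeR adjusted p = 0.0429).

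In all, 2887 of 14596 genes tested were called, 1124 higher and 1763 lower in EF. Besides Saa3 and Cxcl5, genes of largest decrease were the cell adhesion gene Cdh1, at least 77.2-fold lower, and the hormone gene Ostn, at least 69.7-fold lower. The myeloid receptor genes Sirpb1a and Lilra6 were at least 71.1-fold and at least 62.1-fold lower, and all 4 had no count in EF. Without WT 234, the bound of Cdh1 was 41.4-fold. For the leukocyte gene Cd48, the confidence interval of the ratio of EF to WT ran from 7.04e-05 to 0.0021. For the matrix gene Thbs4 it ran from 1.31e-05 to 0.00288. These are binomial intervals on summed counts, as are later ratios given as ranges, and they leave out the spread between libraries. Dync1i1, a dynein chain gene, rose by 8.50 ± 1.35 with a ratio between 131 and 3910 (edgeR adjusted p = 0.00659). Ccn1, a matricellular YAP1 target gene (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981), rose by 1.57 ± 0.41 (edgeR adjusted p = 0.0343), and Prrx1, a limb mesenchyme transcription factor gene (ENSMUSG00000026586, chromosome 1, 163245119 to 163313710), by 1.59 ± 0.43 (edgeR adjusted p = 0.039). Igf2, a fetal growth factor gene (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), was at 285 ± 257 CPM in WT and 3.27 ± 6.07 CPM in EF, a difference of -6.47 ± 1.93 that did not pass (edgeR adjusted p = 0.0524). It passed by DESeq2 (adjusted p = 0.00291), by limma-voom (adjusted p = 0.0262), without library WT 202 (edgeR adjusted p = 0.0379) and without EF 225, where it fell by 10.36 (edgeR adjusted p = 0.00925). Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042) differed by -0.43 ± 1.45 and mouse Fli1 (ENSMUSG00000016087, chromosome 9, 32422204 to 32542861) by -1.09 ± 0.68 (edgeR adjusted p = 0.856 and 0.284). Without EF 225, Igf1 fell by 3.93 and passed (edgeR adjusted p = 0.0149). Neither did Ccn2, Cav1, Igf1r, Trp53, Wwtr1 or Ewsr1 pass, nor Ankrd1 (1.21 ± 0.57), which passed without EF 219 (edgeR adjusted p = 0.0375), and Nr0b1 and Nkx2-2 had too few counts to be tested.

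Of the 22 YAP1/TAZ-TEAD target genes tested, 6 rose, 2 fell and 14 did not pass; adjusted over the list alone, 11 rose and 2 fell. Tgfb2, a growth factor gene, rose by 3.73 ± 0.38, while F3, the coagulation tissue factor gene, and Gadd45a, a growth arrest gene, fell by 3.51 ± 0.66 and 2.24 ± 0.36. The list was called higher (camera adjusted p = 0.0256), with an adjusted p of 0.584 with an estimated correlation and 0.0742 without library EF 225. Among 23 Hippo pathway components 7 rose, 0 fell and 16 did not pass, and 9 rose when adjusted over the list alone; Wwc1, a scaffold of the pathway's kinases, rose by 4.45 ± 0.63. That list was called higher too (camera adjusted p = 0.000191, and adjusted p = 0.602 with an estimated correlation).

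Among 20 interstitial collagen and matrix genes 1 rose, 6 fell and 13 did not pass (1 up and 7 down adjusted over the list alone); the collagen gene Col3a1 fell by 4.96 ± 0.81, the fibrillin gene Fbn1 by 3.66 ± 0.66 and Sparc by 1.89 ± 0.28. Its camera adjusted p was 0.0116, with an adjusted p of 0.551 with an estimated correlation and 0.0822 without library WT 202. Of 12 adipocyte genes 0 rose, 5 fell and 7 did not pass (6 down adjusted over the list alone), among them the lipase gene Lpl, which fell by 6.17 ± 1.06, and the triglyceride synthesis gene Dgat2, which fell by 5.16 ± 0.47. Adipocyte genes had a camera adjusted p of 0.00201, and an adjusted p of 0.144 with an estimated correlation. Of 21 glycolysis and hypoxia genes 0 rose, 8 fell and 13 did not pass (8 down adjusted over the list alone). Glycolysis and hypoxia genes had a camera adjusted p of 0.000349, and an adjusted p of 0.584 with an estimated correlation. The carbonic anhydrase gene Car9 fell by 9.03 ± 0.90, the glucose transporter gene Slc2a1 by 2.48 ± 0.31 and Vegfa by 2.02 ± 0.36.

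Of 16 hematopoietic markers 0 rose, 13 fell and 3 did not pass (14 down adjusted over the list alone). Hematopoietic markers had a camera adjusted p of 1.86e-08, and an adjusted p of 0.365 with an estimated correlation. The macrophage genes Ctss, Lyz2 and Adgre1 changed by -8.17 ± 1.31, -7.71 ± 1.27 and -7.46 ± 1.02. Of 6 osteoclast markers 0 rose, 4 fell and 2 did not pass (6 down adjusted over the list alone), among them Ctsk, which fell by 4.93 ± 0.92. Osteoclast markers had a camera adjusted p of 0.00222, and an adjusted p of 0.37 with an estimated correlation. The hematopoietic markers together held 10700, 30400 and 19400 CPM of the library totals in WT 202, 234 and 237, and 473, 55.5, 57.2 and 71.7 CPM in EF 219, 221, 225 and 229. Counted only among genes with a mean of at least 10 CPM in experiment 2, where these markers summed to 8.11 to 31.1 CPM, 1510 genes were called, 858 higher and 652 lower in EF. Of the lists above, 5 of 19 matrix, 2 of 3 adipocyte and 5 of 17 glycolysis and hypoxia genes were then lower, and 1 matrix gene higher. Of YAP1/TAZ-TEAD targets 6 of 21 were higher and 2 lower, and of Hippo components 7 of 23 were higher. This restriction left 9375 genes tested and was chosen after the data were seen. Experiment 2 held no WT library, so the restriction can by itself favour genes higher in EF.

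The other lists were not called in EF against WT. EWS::FLI1-activated genes had 1 member up and 2 down of 18 (median 0.21, mean -0.18; camera adjusted p = 0.844), including the zinc finger gene Egr2, which fell by 6.31 ± 0.50, and EWS::FLI1-repressed genes 3 up and 5 down of 19 (camera adjusted p = 0.535). The IGF axis had 1 up and 2 down of 17 (camera adjusted p = 0.404), with the insulin receptor substrate gene Irs1 up by 2.78 ± 0.34. Mesenchymal stromal markers had 1 up and 2 down of 18 (camera adjusted p = 0.823). Osteoblast genes had 4 up and 1 down of 9 (camera adjusted p = 0.18) and chondrocyte genes 1 up and 3 down of 9 (0.376). EMT and contractile genes had 1 up and 4 down of 24 and p53 and senescence genes 0 up and 5 down of 17 (camera adjusted p = 0.146 for each). Neural genes had 0 up and 1 down of 9 (median -0.77, mean 0.10, camera adjusted p = 0.378) and endothelial markers 0 up and 1 down of 7 (0.357). Adjusted over the list alone, these counts became 1 up and 2 down for EWS::FLI1-activated, 4 and 6 for EWS::FLI1-repressed, 3 and 5 for the IGF axis and 1 and 2 for mesenchymal lists. They became 4 and 1 for osteoblast, 1 and 3 for chondrocyte, 1 and 5 for EMT, 1 and 5 for p53, 0 and 1 for neural and 0 and 1 for endothelial lists. No proliferation gene of 22 was called by edgeR, against 5 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom (median 1.42, camera adjusted p = 0.108), though the list was called without EF 225 (camera adjusted p = 9.11e-07) or WT 234 (0.0172). No interferon response gene of 22 was called by edgeR, against 2 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom (median 0.12, mean 0.45, tested as lower, camera adjusted p = 0.8). For both lists the count adjusted over the list alone was 0. Myogenic and epithelial markers had 4 and 2 members tested, too few for a test, with 1 member down in each.

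Mitochondrial genes held 4.06, 5.13, 8.43 and 5.77% of the counts in EF 219, 221, 225 and 229 and 3.00, 1.63 and 3.52% in WT 202, 234 and 237, without overlap, so this share cannot be told apart from genotype. The 10 most abundant genes held 16.8% in EF 225 and 7 to 10.7% in the other 6. Sex was not balanced between the groups. The Y-linked Ddx3y stood at 87.4 and 43.1 CPM of the library total in WT 202 and 234. It was at 0.134 CPM in WT 237 and at most 0.0656 CPM in EF, so sex is partly confounded with genotype. Single libraries weighed on this comparison: 5087 genes were called without WT 202, 1673 without EF 221, 1580 without EF 229, 1275 without WT 234 and 1219 without WT 237, and DESeq2 called 4886. The calls of Yap1 and Ccn1 were lost in 6 of the 7 omissions and that of Prrx1 in 5, with edgeR adjusted p for Yap1 from 0.00465 without WT 202 to 0.175. The call of Yap1 was also lost with no filter on low counts (0.0641). By contrast, Saa3, Cxcl5, Cdkn2a, Pgr, Tgfb2, Wwc1 and the matrix, lipid, hypoxia and blood cell genes named above kept their calls in all 7. The sizes of some changes moved: without EF 219, Ctss, Lyz2 and Adgre1 stood at -10.26, -9.57 and -9.23, without EF 225 Lpl at -7.56, and without WT 202 Dync1i1 at 11.24.

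**Figure D1:**
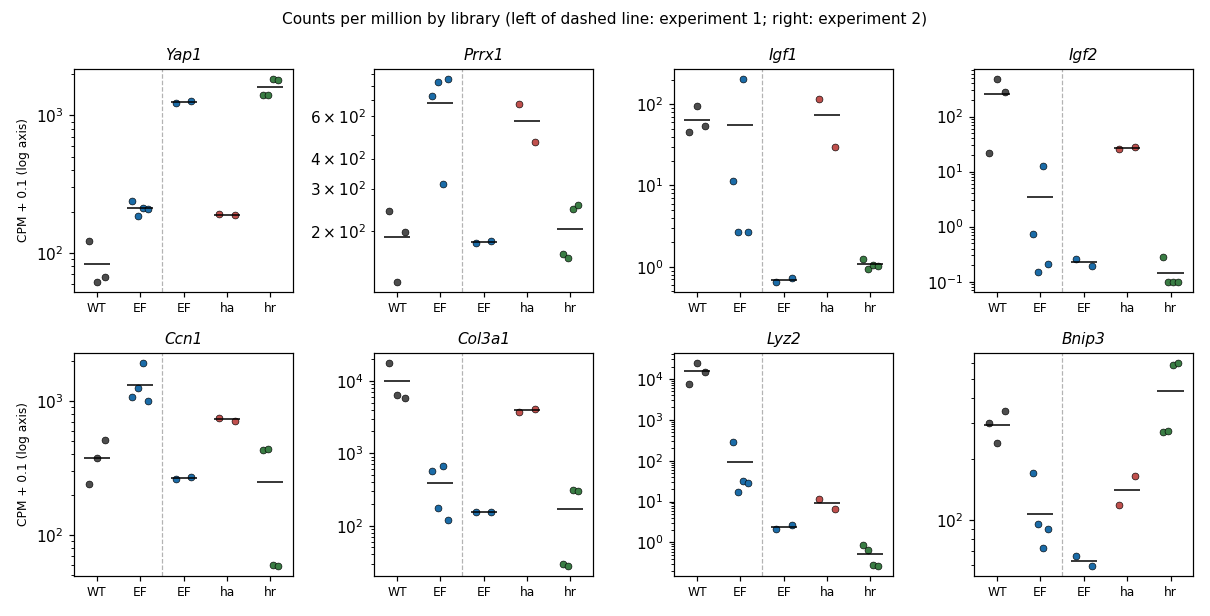
CPM of the library total plus 0.1 (log axes) of Yap1, Prrx1, Igf1, Igf2, Ccn1, Col3a1, Lyz2 and Bnip3; each point is a library and each bar the group mean, with experiment 1 left and experiment 2 right of the dashed line. Yap1 lies at 188 and 192 CPM in the ha libraries and at 1240 CPM or above in the EF and hr libraries of experiment 2.

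Experiment 2 compared ha with EF cells. Yap1 fell by 2.73 ± 0.18 from 1262 ± 19.3 CPM in EF (n = 2) to 191 ± 7.73 CPM in ha (n = 2; edgeR adjusted p = 0.000122). Igf1 rose by 6.90 ± 0.69 from 0.590 ± 0.0439 to 71.5 ± 56.8 CPM (edgeR adjusted p = 0.000457), and by 5.71 without ha library 2 and 7.54 without ha library 1. Igf2 rose by 7.62 ± 0.67, with a ratio between 71.7 and 1020 (edgeR adjusted p = 0.000307). Postn, a matricellular protein gene, rose by 7.95 ± 0.36 (edgeR adjusted p = 2.69e-05) and Oasl2, an interferon-induced gene, by 5.09 ± 0.45 (edgeR adjusted p = 0.000316).

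Of 13998 genes tested, 5961 were called, 3214 higher and 2747 lower in ha. The genes of largest increase included the adhesion gene Sdk1, with a ratio between 944 and 208000, the ubiquitin ligase genes Fbxl7, at least 177-fold higher, and Rnf144a, at least 130-fold, and the matrix genes Egflam, at least 181-fold, and Col27a1, at least 123-fold. Without ha library 2, the bound of Egflam was 108-fold. The protease gene Prss12 was at least 113-fold higher, and Xist, the RNA of the inactive X chromosome, rose by 11.56 ± 1.32 from 0.217 ± 0.194 CPM. Genes of largest decrease included the epithelial keratin gene Krt19, which fell by 6.20 ± 0.21, the glutathione transferase gene Gsta1, with a ratio between 0.000356 and 0.0107, Slurp1, Cldn9, Rab3b and Lpl, which fell by 6.75 ± 0.61, 6.39 ± 1.08, 6.28 ± 0.65 and 6.27 ± 0.58, and the pseudogene Rpl30-ps10, whose reads may belong to other copies. Prrx1 rose by 1.67 ± 0.28 and Wwtr1, the paralog of Yap1, by 0.59 ± 0.09 (edgeR adjusted p = 0.00314 and 0.00245). Mouse Fli1 rose by 1.80 ± 0.36 (edgeR adjusted p = 0.00634, and 0.0571 without EF library 1), and Ewsr1 changed by -0.56 ± 0.14, a call lost without EF library 1, EF library 2 or ha library 1 (edgeR adjusted p = 0.0146, at most 0.0806). These are the mouse genes; the fusion is not a feature of its own in the count table. Ccn1, Ccn2, Ankrd1, Cav1, Igf1r and Trp53 did not pass, with Ccn1 at a difference of 1.47 ± 1.00 (edgeR adjusted p = 0.271). In a fit of only the groups compared, Ccn1, Ankrd1, Cav1, Trp53 and Igf1r passed (edgeR adjusted p = 0.00421, 0.00726, 0.0416, 0.0435 and 0.0471). Ccn2 went from 1.45 to -0.12 without ha library 2. Cdkn2a had no count in any library of experiment 2.

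Among 16 IGF axis genes 11 rose, 0 fell and 5 did not pass (12 up and 1 down adjusted over the list alone), with the IGF2 clearance receptor gene Igf2r up by 1.56 ± 0.10 and Irs1 by 1.90 ± 0.14. The IGF axis had a camera adjusted p of 7.12e-05, and an adjusted p of 0.118 with an estimated correlation. Of 20 collagen and matrix genes 16 rose, 1 fell and 3 did not pass (16 and 1 adjusted over the list alone), among them Fbn1 by 2.26 ± 0.23, the proteoglycan gene Bgn by 1.68 ± 0.13 and Col1a2 by 1.26 ± 0.14. Collagens and matrix had a camera adjusted p of 6.37e-05, and an adjusted p of 0.118 with an estimated correlation. Of 22 interferon response genes 21 rose, 0 fell and 1 did not pass (21 adjusted over the list alone), with Xaf1 up by 2.29 ± 0.16 and the RNA sensor gene Ddx58 by 1.44 ± 0.11. Interferon response genes had a camera adjusted p of 3.57e-08, and an adjusted p of 0.197 with an estimated correlation. Of 21 EMT and contractile genes 12 rose, 1 fell and 8 did not pass (14 and 1 adjusted over the list alone). EMT and contractile genes had a camera adjusted p of 0.00272, and an adjusted p of 0.308 with an estimated correlation. The cadherin gene Cdh11 rose by 9.12 ± 0.59, the myosin light chain gene Myl9 by 5.41 ± 0.51 and the transcription factor gene Zeb1 by 1.83 ± 0.13. Of 18 EWS::FLI1-repressed genes, 12 of whose 21 members are also in another list, 13 rose, 1 fell and 4 did not pass (15 and 1 adjusted over the list alone), with the IGF-binding protein gene Igfbp3 up by 4.66 ± 0.28. EWS::FLI1-repressed genes had a camera adjusted p of 0.000349, and an adjusted p of 0.118 with an estimated correlation. Proliferation genes went the other way: of 22, 0 rose, 20 fell and 2 did not pass (20 adjusted over the list alone). The mitotic kinase genes Plk1 and Aurkb had log2 fold changes of -1.97 ± 0.20 and -1.88 ± 0.17. Proliferation genes had a camera adjusted p of 1.74e-07, and an adjusted p of 0.602 with an estimated correlation.

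YAP1/TAZ-TEAD targets were not called as a list (camera adjusted p = 0.205): 7 rose, 2 fell and 13 of 22 did not pass, the same counts as adjusted over the list alone, with the RNA-binding protein gene Rbms3 up by 3.44 ± 0.17, the matrix gene Ccdc80 by 3.02 ± 0.18 and Tgfb2 by 2.67 ± 0.33. Hippo components had 4 up and 7 down of 23 (camera adjusted p = 0.376), with Wwc1 changed by -2.77 ± 0.36. EWS::FLI1-activated genes had 5 up and 5 down of 17 (median -0.16, mean 1.24; camera adjusted p = 0.73), among them the telomerase gene Tert, at least 28.2-fold higher, and Steap1, which fell by 3.29 ± 0.26. Mesenchymal markers had 6 up and 4 down of 18 (camera adjusted p = 0.8). Osteoblast genes had 2 up and 0 down of 8 (camera adjusted p = 0.404), chondrocyte genes 3 up and 1 down of 9 (0.425), and adipocyte genes 1 up and 1 down of 6 (0.8). Endothelial markers had 1 up and 0 down of 7 (camera adjusted p = 0.464) and neural genes 2 up and 1 down of 6 (median -0.10, mean 0.23; 0.897), the last with the adhesion gene Ncam1 up by 2.41 ± 0.13. Glycolysis and hypoxia genes had 5 up and 3 down of 20 (0.462), and p53 and senescence genes 0 up and 4 down of 15 (0.134), including the apoptosis gene Bax, which fell by 1.32 ± 0.14. Adjusted over the list alone, glycolysis had 5 up and 2 down, p53 had 0 up and 2 down, osteoclast markers had 2 up and 2 down, and the counts of the other lists in this paragraph were the same. Too small for a test were hematopoietic markers, with 2 of 3 up, myogenic with 1 up and 2 down of 3, epithelial with 3 of 3 down and osteoclast with 1 up and 2 down of 4.

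With the close EF and hr pairs summed, a choice made after the data were seen, 736 genes were called in ha against EF, and 47 of the 85 called genes that the naming rule selected were kept. EF is then a single sample, assumed to vary like ha and hr. Median log2 fold changes barely moved. In the main and the summed fit they were 2.39 and 2.36 for collagens and matrix and 3.17 and 3.14 for interferon response. They were 1.27 and 1.24 for the IGF axis, 1.79 and 1.78 for EMT and contractile, and 1.90 and 1.86 for EWS::FLI1-repressed genes. Proliferation genes had -1.42 and -1.45. Members called in that fit were 3 up of 20 collagen and matrix genes, 9 up of 22 interferon response genes, 7 up of 16 IGF axis genes, 4 up of 24 EMT and contractile genes, 2 up of 18 EWS::FLI1-repressed genes and 4 down of 22 proliferation genes. Without EF library 1 or 2, 3070 and 3106 genes were called. The calls of Prrx1, Wwtr1, Fli1 and Ewsr1 were lost with pairs summed (edgeR adjusted p = 0.0766, 0.194, 0.129 and 0.203), as were those of Prss12, Bgn and Col1a2 (0.0723, 0.0546 and 0.105), whereas Yap1, Igf1, Igf2, Postn, Oasl2, Plk1, Cdh11 and Igfbp3 kept their calls with pairs summed and in every omission. Among the changes that moved in size, Postn rose by 9.27 without EF library 2 and Xist by 12.86 without EF library 1. Without ha library 2, Slurp1, Lpl and Cldn9 stood at -7.97, -8.25 and -5.30, and without ha library 1 Rab3b and Cldn9 at -7.33 and -10.26. The call of Cldn9 was lost in 1 of 12 alternatives, though in no omission of a library.

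The next comparison set hr against EF. The glycolytic enzyme gene Pgk1 rose by 1.60 ± 0.13 from 792 ± 20 CPM in EF (n = 2) to 2406 ± 59.2 CPM in hr (n = 4; edgeR adjusted p = 0.0051), Slc2a1 by 1.64 ± 0.18 and the mitophagy gene Bnip3 by 2.79 ± 0.43 (edgeR adjusted p = 0.00772 and 0.0158). Krt19 rose by 1.70 ± 0.12 (edgeR adjusted p = 0.00231), and Fbn1 fell by 1.86 ± 0.19 (edgeR adjusted p = 0.00638). Yap1 stood at 1613 ± 224 CPM in hr and 1262 ± 19.3 CPM in EF and did not pass (0.35 ± 0.15; edgeR adjusted p = 0.179).

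Of 13998 genes tested, 973 were called, 543 higher and 430 lower in hr. Xist rose by 10.35 ± 1.27 (edgeR adjusted p = 0.00899), and by 11.65 without EF library 1. The milk protein gene Csn3 rose by 4.20 ± 0.71 and the keratin gene Krt14 by 3.45 ± 0.57. The matrix gene Ltbp2 rose by 3.26 ± 0.55 and the oxidative folding gene Ero1l by 2.74 ± 0.40. Slpi, a protease inhibitor gene, fell by 3.39 ± 0.38, Fgf7 by 2.17 ± 0.46, Lpl by 2.08 ± 0.36 and Serpina3g by 1.94 ± 0.24. None of Igf1, Igf2, Igf1r, Prrx1, Ccn1, Ccn2, Ankrd1, Cav1, Wwtr1, Fli1, Ewsr1 or Trp53 passed in hr against EF by edgeR. Ccn1 differed by -0.10 ± 0.84, which averages hr libraries on opposite sides of EF. Its mean was 58.8 CPM in hr libraries with first title number 1, 440 CPM in those with 2 and 267 CPM in EF. Ccn2 (8.68, 68.9 and 43.2 CPM) and Ankrd1 (69.8, 225 and 128 CPM) were split likewise.

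Of 20 glycolysis and hypoxia genes 16 rose, 0 fell and 4 did not pass (18 up adjusted over the list alone), among them Pfkp by 1.31 ± 0.13 and Pgam1 by 1.10 ± 0.12. Glycolysis and hypoxia genes had a camera adjusted p of 1.86e-13, and an adjusted p of 0.263 with an estimated correlation. Of 22 proliferation genes 0 rose, 4 fell and 18 did not pass (9 down adjusted over the list alone), with the checkpoint gene Bub1b down at -0.97 ± 0.18. Proliferation genes had a camera adjusted p of 3.85e-06, and an adjusted p of 0.602 with an estimated correlation. Of 6 neural genes 3 rose, 0 fell and 3 did not pass (3 adjusted over the list alone). Neural genes had a camera adjusted p of 0.00633, and an adjusted p of 0.193 with an estimated correlation. These were the enolase gene Eno2, also a glycolytic enzyme, by 2.11 ± 0.27, the tubulin gene Tubb3 by 1.73 ± 0.24 and Ncam1 by 1.01 ± 0.12.

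The remaining lists were not called in hr against EF. YAP1/TAZ-TEAD targets had 3 up and 1 down of 22 (camera adjusted p = 0.475). For 10 of these 22 genes, hr libraries with first title number 1 and 2 lay on opposite sides of EF. Their median differences from EF were -0.15 and 0.57. Opposite sides were also seen for 8 of 20 collagen and matrix and 10 of 22 interferon response genes. Among the 20 glycolysis and hypoxia genes there were 0. Lists not called can thus average unlike hr libraries. Hippo components had 0 up and 2 down of 23 (camera adjusted p = 0.446), with the adaptor gene Amotl1 down at -0.85 ± 0.10. EWS::FLI1-activated genes had 1 up and 1 down of 17 (median -0.17, mean 0.62, camera adjusted p = 0.683), with Tert at least 5.3-fold higher, and EWS::FLI1-repressed genes 3 up and 0 down of 18 (0.288). The IGF axis had 2 up and 1 down of 16 (camera adjusted p = 0.491), mesenchymal markers 0 up and 2 down of 18 (0.162). Osteoblast genes had 1 up and 1 down of 8 (median -0.26, mean 0.03, camera adjusted p = 0.535), chondrocyte genes 0 up and 1 down of 9 (0.357), and adipocyte genes 0 up and 1 down of 6 (0.412). Collagens and matrix had 1 up and 2 down of 20 (median -0.03, mean 0.21, camera adjusted p = 0.341), interferon response genes 1 up and 0 down of 22 (0.518) and p53 and senescence genes 1 up and 0 down of 15 (0.285). Adjusted over the list alone, YAP1/TAZ-TEAD targets had 4 up and 2 down, the IGF axis 3 up and 2 down, EWS::FLI1-activated genes 1 up and 2 down, adipocyte genes 1 up and 1 down, osteoclast markers 0 up and 2 down, interferon genes 0, and the others named here the same counts. No EMT and contractile gene of 21 was called by edgeR, against 3 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.367), and no endothelial marker of 7, against 1, 0 and 0 (camera adjusted p = 0.743). Too small for a test were hematopoietic markers with 1 of 3 down, epithelial with 2 of 3 up, osteoclast with 1 of 4 down and myogenic with 0 of 3 called by edgeR, against 2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom.

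The edgeR calls of hr against EF rested on counting libraries that lay close together as separate replicates, whereas DESeq2 kept some calls. The changes themselves barely moved. Glycolysis and hypoxia genes had a median of 1.29 in the main fit (20 tested). With the close pairs summed, where EF is a single sample, it was 1.30 (21 tested). Summing leaves fewer libraries, so lost calls alone do not show that changes are absent. With only the hr libraries summed, edgeR called 0 genes (2323 at an unadjusted p under 0.05, 597 by DESeq2, 0 by limma-voom). Without hr library 2-1, 2-2, 1-1 or 1-2 it called 332, 366, 378 and 379. Fits of only these groups called 1927 and DESeq2 1750. None of the 50 called genes that the naming rule selected kept its call with the pairs summed.

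The hr and ha cells were then compared directly, which also tests whether their differences from EF differ. Yap1 was 3.08 ± 0.17 higher in hr on the log2 scale, 1613 ± 224 CPM (n = 4) against 191 ± 7.73 CPM (n = 2; edgeR adjusted p = 4.2e-05). Igf1 fell by 6.20 ± 0.49 to 0.969 ± 0.129 CPM in hr and Igf2 by 9.04 ± 0.56 (edgeR adjusted p = 0.000142 and 6.45e-05). Without ha library 2, Igf1 stood at -5.01, and without hr library 2-2, the only hr library with a count for it, Igf2 stood at -11.46. The laminin gene Lama4 fell by 12.51 ± 0.31, with a ratio between 2.97e-06 and 0.000654, and Postn changed by -9.78 ± 0.31 (edgeR adjusted p = 1.98e-06 and 4.48e-06). Krt19 rose by 7.90 ± 0.20 (edgeR adjusted p = 1.98e-06).

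Of 13998 genes tested, 5517 were called, 2505 higher and 3012 lower in hr. Besides Krt19, the largest increases were those of the ligand gene Wnt7a, at least 95.4-fold higher, of Slurp1, which rose by 7.95 ± 0.60, and of Krt14, Psca and Gsta1, with ratios between 55.4 and 12300, 71.4 and 2140, and 51.5 and 1550. The tight junction gene Cldn9 and the laminin gene Lamb3 rose by 6.98 ± 1.03 and 6.08 ± 0.31. Besides Lama4, the largest decreases included those of the deiodinase gene Dio2, at least 186-fold lower, Pde7b, at least 152-fold, Dync1i1, at least 93.7-fold, the protease gene Tll1, at least 62.8-fold, Tril, at least 72.1-fold, and Sdk1, with a ratio between 5.72e-05 and 0.000811. Without ha library 2, the bounds of Dio2, Pde7b and Tll1 were 66.8-fold, 69.9-fold and 37.9-fold. The calls of Wnt7a and Dio2 were lost in 2 and 1 of 15 alternatives, though in no omission of a library. Prrx1 fell by 1.49 ± 0.23, Fli1 by 2.14 ± 0.30 and Wwtr1 by 0.40 ± 0.08 (edgeR adjusted p = 0.00225, 0.00146 and 0.00632). Igf1r, the IGF-1 receptor gene, changed by -0.74 ± 0.18 and the caveolin gene Cav1 by 0.81 ± 0.20 (edgeR adjusted p = 0.0149 and 0.0142), calls lost without ha library 1 (0.0692) and ha library 2 (0.0755). Ccn1, Ccn2, Ewsr1 and Trp53 did not pass, nor did Ankrd1 (edgeR adjusted p = 0.0843), which passed by DESeq2 (adjusted p = 0.013) and without hr library 1-1 (0.042) or 1-2 (0.0365).

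Of 20 collagen and matrix genes 0 rose, 17 fell and 3 did not pass (18 down adjusted over the list alone). Among them, Fbn1 had a log2 fold change of -4.12 ± 0.19 and the collagen gene Col5a1 one of -1.30 ± 0.10. Collagens and matrix had a camera adjusted p of 7.47e-07, and an adjusted p of 0.118 with an estimated correlation. Interferon response genes fell in 21 of 22 members, with 0 up and 1 that did not pass (21 adjusted over the list alone), among them Oasl2 at -4.23 ± 0.32 and Xaf1 at -1.68 ± 0.13. Interferon response genes had a camera adjusted p of 2.04e-09, and an adjusted p of 0.179 with an estimated correlation. In the IGF axis 1 of 16 genes rose, 11 fell and 4 did not pass (1 and 12 adjusted over the list alone), with Irs1 at -1.80 ± 0.12 and Igf2r at -1.50 ± 0.08. The IGF axis had a camera adjusted p of 1.88e-05, and an adjusted p of 0.118 with an estimated correlation. EMT and contractile genes had 2 up, 13 down and 6 not passing of 21 (2 and 14 adjusted over the list alone), with Cdh11 at -7.75 ± 0.39 and Myl9 at -5.28 ± 0.38. EMT and contractile genes had a camera adjusted p of 0.00423, and an adjusted p of 0.327 with an estimated correlation. EWS::FLI1-repressed genes had 2 up, 13 down and 3 not passing of 18 (2 and 14 adjusted over the list alone), with the thrombospondin gene Thbs1 at -5.30 ± 0.54 and Igfbp3 at -3.26 ± 0.19. EWS::FLI1-repressed genes had a camera adjusted p of 0.000874, and an adjusted p of 0.118 with an estimated correlation.

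Higher in hr than in ha were glycolysis and hypoxia genes, with 14 up, 1 down and 5 not passing of 20 (15 and 2 adjusted over the list alone). Glycolysis and hypoxia genes had a camera adjusted p of 6.37e-05, and an adjusted p of 0.584 with an estimated correlation. Pfkp rose by 1.80 ± 0.13 and the lactate dehydrogenase gene Ldha by 1.46 ± 0.13. Proliferation genes had 13 up, 0 down and 9 not passing of 22 (15 up adjusted over the list alone), with Aurkb up by 1.33 ± 0.15 and Birc5 by 1.30 ± 0.21. Proliferation genes had a camera adjusted p of 8.34e-05, and an adjusted p of 0.614 with an estimated correlation. Of 15 p53 and senescence genes 8 rose, 0 fell and 7 did not pass (9 up adjusted over the list alone), with the nuclease gene Aen up by 1.58 ± 0.20 and Bax by 1.24 ± 0.12. The p53 and senescence list had a camera adjusted p of 0.00423, and an adjusted p of 0.584 with an estimated correlation.

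YAP1/TAZ-TEAD targets were not called in hr against ha (camera adjusted p = 0.148): 2 rose, 7 fell and 13 of 22 did not pass, the same counts as adjusted over the list alone, with Tgfb2 at -2.92 ± 0.26, Rbms3 at -2.54 ± 0.12 and Ccdc80 at -2.51 ± 0.14. Hippo components had 5 up and 5 down of 23 (camera adjusted p = 0.676), with Wwc1 up by 2.66 ± 0.33 and Amot, an adaptor that binds YAP1, at -1.01 ± 0.10. EWS::FLI1-activated genes had 5 up and 6 down of 17 (median 0.30, mean -0.62, tested as higher, camera adjusted p = 0.8), with the cyclin gene Ccnd1 up by 2.78 ± 0.43 and Npy1r at -6.60 ± 0.65. Mesenchymal markers had 2 up and 6 down of 18 (median 0.03, mean -0.52; camera adjusted p = 0.518), osteoblast genes 1 up and 5 down of 8 (camera adjusted p = 0.195) and chondrocyte genes 0 up and 4 down of 9 (0.136, and 0.0327 without hr 1-2). Adipocyte genes had 1 up and 1 down of 6 (camera adjusted p = 0.77), neural genes 2 up and 1 down of 6 (0.357) and endothelial markers 0 up and 2 down of 7 (0.537). Adjusted over the list alone, mesenchymal markers had 2 up and 7 down, chondrocyte genes 0 and 5, adipocyte genes 1 and 2, neural genes 3 and 1, myogenic genes 2 and 1, osteoclast markers 1 and 2, and the others named here the same counts. Hematopoietic, myogenic, epithelial and osteoclast markers were too small for a test, with 1 up and 2 down of 3, 1 up and 1 down of 3, 3 of 3 up and 1 up and 1 down of 4.

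With the close pairs summed, 1272 genes were called in hr against ha, and 67 of the 89 called genes that the naming rule selected were kept; with only the hr libraries summed the count was 3140. Members called with the close pairs summed were 7 down of 20 collagen and matrix genes, 14 down of 22 interferon response genes, 8 down of 16 IGF axis genes, 4 down of 24 EMT and contractile genes and 4 down of 18 EWS::FLI1-repressed genes. Called higher in that fit were 5 of 21 glycolysis and hypoxia, 3 of 22 proliferation and 2 of 15 p53 and senescence genes. With pairs summed the calls of Wwtr1, Fli1, Igf1r and Cav1 were lost (edgeR adjusted p = 0.256, 0.0526, 0.134 and 0.125), and that of Wwtr1 also with the hr libraries summed (0.0713) and with no filter (0.0538). Yap1, Igf1, Igf2, Prrx1, Lama4, Postn and Krt19 kept their calls in both and in every omission of a library. In size, Lama4 moved to -14.13 without hr library 2-1, Slurp1 to 9.17 without ha library 2, and Cldn9 to 5.88 and 10.84 without ha library 2 and 1.

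**Figure D2:**
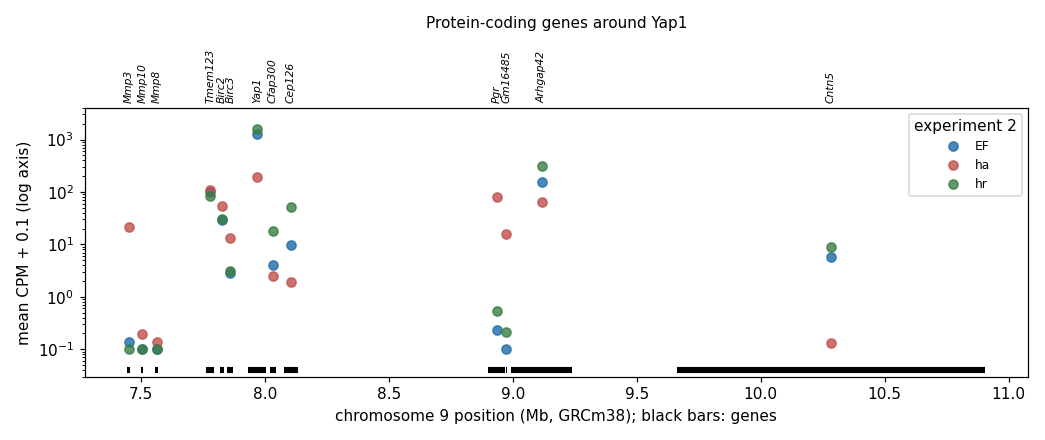
Mean CPM of the library total plus 0.1 (log axis) in EF, ha and hr of experiment 2 for protein-coding genes on chromosome 9 around Yap1, by position in Mb on GRCm38, with black bars for the genes. Yap1, Cfap300, Cep126, Arhgap42 and Cntn5 lie higher in hr than in ha, and Birc2, Birc3 and Pgr lower.

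The genes that separated EF from WT most strongly in experiment 1 were followed in experiment 2. Of the 200 genes of lowest p that were higher in EF, 190 were tested; 3 rose and 16 fell in hr against EF, and the set was called lower (median -0.16; camera adjusted p = 0.00314, and adjusted p = 0.283 with an estimated correlation). In hr against ha 25 rose and 73 fell (camera adjusted p = 0.00856, and adjusted p = 0.297 with an estimated correlation), and in ha against EF 61 rose and 43 fell (camera adjusted p = 0.366). Of the 200 genes lower in EF, 92 were tested; 33 rose and 8 fell in ha against EF (median 0.68; camera adjusted p = 0.0161, and adjusted p = 0.0865 with an estimated correlation), 5 rose and 3 fell in hr against EF (camera adjusted p = 0.0416, and adjusted p = 0.0865 with an estimated correlation), and 13 rose and 29 fell in hr against ha (camera adjusted p = 0.199). With all genes called in experiment 1 in place of the 200, the camera adjusted p of the 4 sets called rose to 0.0634 to 0.312.

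The ha and hr comparisons share the 2 EF libraries. Among the 13998 genes, 378 were called higher and 300 lower in both, and 70 in opposite directions; independent lists of these sizes would share 125 and 84.4. By limma, 357 were called higher and 185 lower in both. In 1000 simulations every library, EF included, was drawn from the same mean for each gene, so no gene differed. Limma then shared a median of 0 and at most 1 higher and 3 lower. Since hardly any gene can be called there, this count cannot show what overlap the shared EF libraries give when many genes are called. The covariance of the edgeR log2 fold changes was 0.828. On limma's scale it was 0.371 against a simulated median of 0.102, a difference of 0.269, and the correlation across genes, which are not independent replicates, was 0.409 against a simulated 0.575. With 1 EF library for ha and the other for hr, a test chosen after the data were seen, the edgeR covariance over 13994 genes was 0.796 and 0.793 against 0.827 with shared controls. The EF libraries lay close together, so this leaves in place any feature that both share.

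**Figure D3:**
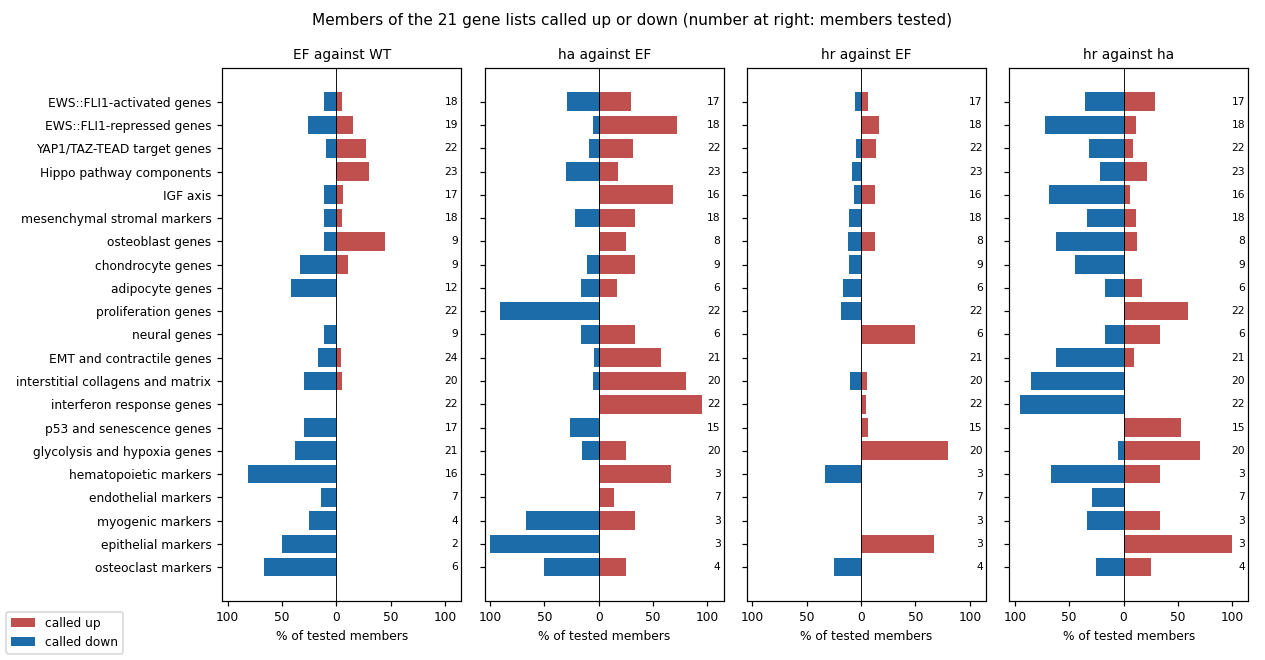
Share of the tested members of each of the 21 gene lists that was called higher (red, to the right) or lower (blue, to the left) by edgeR, as a percent of the members tested, with the number tested at the right of each row, for the 4 comparisons. Of 22 interferon response genes 21 are higher in ha than in EF and 21 lower in hr than in ha, and of 20 glycolysis and hypoxia genes 16 are higher in hr than in EF.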

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

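In groups of 4 libraries, 213 sets of values were examined for 1 library far from the other 3 (Dixon's test at 95%), and 19 were found; chance flags about 1 in 20 groups. The genes examined were widened from the key and largest-change genes to every named gene after the first values were seen, and no explanation was tested for these values. All gene values are TMM-normalised CPM.

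Library EF 225 of experiment 1 was far above the other 3 EF libraries for Igf1 (198 CPM, others 2.35 to 10.1), Igf2 (12.4, others 0.048 to 0.564), Ptprq (194, others 6.25 to 16), F3 (42, others 7.05 to 12), Pappa (7.7, others 0.384 to 0.938) and Lpl (19.9, others 1.82 to 4.15). Library EF 219 was far above the others for Nptx1 (719 CPM, others 3.79 to 20.3) and for genes of the myeloid lineage: Lyz2 (254, others 16.1 to 30.2), Ctss (19.6, others 0.911 to 2.24), Adgre1 (3.79, others 0.288 to 0.513) and Tnfrsf11a (1.18, others 0 to 0.174). Library EF 229 stood above the others for Irs1 (94.3 CPM, others 66.8 to 70.8) and was the only EF library with a count for Thbs4 (0.0348 CPM, others 0).

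Among the hr libraries, 2-1 had the highest total (14.2 mega-counts, others 11.4 to 11.7) and the lowest Igfbp7 (23 CPM, others 24.6 to 24.8). Single counts or few counts set 1 library apart for Igf2 (2-2, 0.178 CPM, others 0), Lama4 and Dkk2 (2-1, 0.0713 CPM each, others 0) and Comp (1-2, 0.17 CPM, others 0).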

How the results depend on the processing

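Summing the close pairs, separate EF controls for ha and hr, and restricting genes by chromosome or by expression in experiment 2 were chosen after the data were seen; the other alternatives were planned. Over all alternatives, 3755 values of named genes kept their side of the threshold, 14 gained a call and 658 lost one; for gene lists these were 601, 19 and 27, and 0 results reversed. Unless stated, the cause of a change was not tested. Where an omission, or the sum of the EF pair, leaves a group with 1 library, that library is assumed to vary like the other groups.

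In EF against WT, 2887 genes became 4886 with DESeq2 and 1510 among genes expressed in experiment 2, where fewer genes were tested (56.8% higher, against 38.9%). As experiment 2 held no WT library, this restriction can by itself raise the share higher in EF. Leave-outs gave 1219 to 5087 (WT 202 5087, EF 221 1673, EF 229 1580, WT 234 1275, WT 237 1219), and 31 of 76 called named genes were lost in at least 1 omission. In ha against EF, 5961 became 736 with close pairs summed and 3310 at a log2 fold change of at least 1; leave-outs gave 3070 (EF 1) and 3106 (EF 2) to 5481, and 25 of 85 named calls were lost in some omission. In hr against EF, 973 became 1750 with DESeq2, 1927 with only these groups fitted, 339 at a log2 fold change of at least 1 and 322 with the title number as a block; block fits gave 5232 in ha against EF and 4686 in hr against ha. Library deviations paired by that number correlated at 0.006 (EF and ha), 0.013 (EF and hr) and 0.001 (hr and ha), so the numbers showed no pairing. In hr against EF edgeR called 0 genes with close pairs summed (797 of 15959 at an unadjusted p under 0.05, DESeq2 99, limma-voom 0) and 0 with the hr libraries summed by first number (2323 of 14111, DESeq2 597, limma-voom 0). Leave-outs gave 0 (EF 1, 1918 unadjusted, DESeq2 273, limma-voom 0; EF 2, 1888, 259 and 0) to 379 (hr 1-2), with 378, 332 and 366 without hr 1-1, 2-1 and 2-2; all 50 named calls were lost in some omission and with pairs summed. In hr against ha, 5517 became 1272 with close pairs summed, 3140 with hr summed and 2640 at a log2 fold change of at least 1; 12 of 89 named calls were lost in some omission. Summing leaves fewer libraries.

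All 24 of 70 list calls ended with an estimated correlation. In 6 of the 24 the estimate lay below the preset 0.01, so that members moving together does not account for these losses. With an estimated correlation, camera also takes its degrees of freedom from the libraries in place of the genes. With so few libraries this raises p by itself. How much of each loss it accounts for was not tested. For the IGF axis in ha against EF the estimate was -0.038, yet the unadjusted camera p went from 1.12e-05 to 0.00528. A call lost with an estimated correlation therefore does not by itself show that members move together. Adjusted p were then 0.584 (YAP1/TAZ-TEAD), 0.602 (Hippo), 0.144 (adipocyte), 0.551 (collagens), 0.584 (glycolysis), 0.365 (hematopoietic) and 0.37 (osteoclast) in EF against WT. In ha against EF they were 0.118 (EWS::FLI1-repressed, IGF axis, collagens), 0.602 (proliferation), 0.308 (EMT) and 0.197 (interferon), and in hr against EF 0.602 (proliferation), 0.193 (neural) and 0.263 (glycolysis). In hr against ha they were 0.118 (EWS::FLI1-repressed, IGF axis, collagens), 0.614 (proliferation), 0.327 (EMT), 0.179 (interferon) and 0.584 (p53, glycolysis). Fry, which tests whether a list moves one way and does not compare it with other genes, passed lists that camera did not: in EF against WT EWS::FLI1-repressed 0.00271, osteoblast 0.0147, EMT 0.00733, p53 0.0147 and endothelial 0.0347, and in ha against EF YAP1/TAZ-TEAD 0.000446, osteoblast 0.00929, neural 0.00678 and endothelial 0.0341. In hr against EF it passed EWS::FLI1-repressed 0.0341 and IGF axis 0.0189 and not proliferation (0.0758), and in hr against ha it passed YAP1/TAZ-TEAD 0.000446, osteoblast 0.00257, chondrocyte 0.0119 and neural 0.00733.

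Leave-outs of EF against WT gave camera adjusted p of 0.0118 to 0.0742 for YAP1/TAZ-TEAD (lost without EF 225), 0.00437 to 0.0822 for collagens (lost without WT 202) and 9.11e-07 (without EF 225; 0.0172 without WT 234) to 0.538 for proliferation. Chondrocyte genes in hr against ha had 0.0327 (without hr 1-2) to 0.211, and 0.0362 with close pairs summed. For the genes followed from experiment 1, an estimated correlation gave 0.0865 (lower genes in ha and in hr against EF), 0.283 (higher genes, hr against EF) and 0.297 (higher genes, hr against ha), and all called genes 0.0693 (lower, ha against EF), 0.0634 (lower and higher, hr against EF) and 0.312 (higher, hr against ha). Lower genes in hr against EF had 0.166 with genes chosen without library 221 and 0.054 with close pairs summed. Calls shared by ha and hr at a log2 fold change of at least 1 were 161 higher and 36 lower, and the covariance of the effects was 0.796 and 0.793 with separate EF controls against 0.827. A count of 0 allowed up to 0.112 to 0.268 CPM by library.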

Other observations

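The tests of other splits and of library scaling were set before their results were seen; the tests of neighbouring genes, the paralog, blood cell markers and nearness to ha were chosen after. Of the 35 splits of the 7 libraries of experiment 1 into 3 and 4, only 1, the real split, called as many as 2887 genes. The highest of the others called 63. The smallest share that 35 splits allow is 1 in 35. The test thus argues against chance assignment of libraries for this count but cannot exclude it. Every other split also mixes WT and EF libraries, so the test does not tell genotype from blood cells or sex.

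Yap1 was higher in EF and hr than in ha. The paralog Wwtr1 lay the other way, at -0.40 between hr and ha, which argues against shared reads raising both genes. Reads shifted from Wwtr1 to Yap1 would also lower Wwtr1, so the direction does not speak against such a shift. In CPM of the library total, Wwtr1 held only 169 and 176 in ha, where Yap1 held 188 and 192. Yap1 held 1240 or more in EF and hr, which is more than such a shift could give. Scaling with DESeq2 size factors left the difference at 3.08, but moved the median of all genes only from -0.004 to -0.002, so it was no test of scaling, which stays open. Neighbours on chromosome 9 also differed: the window of Birc3, Yap1, Gm45494, Cfap300 and Cep126 had a median of 2.86, which did not pass the limit of 4.87 from shuffled gene orders; since that limit lies above the 3.08 of Yap1 itself, a window moving just as Yap1 does could not have passed, and the bound was set aside after this was seen. Birc2 and Pgr nearby were lower in hr (-0.85 and -7.47) and Arhgap42 higher (2.26). A copy number difference, a regulatory difference and a difference set by the ha and hr genotypes may each be present and stay open, as no DNA was analysed here.

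Hematopoietic markers were lower in EF than in WT, with 14 of 16 tested markers higher in all 3 WT than in all 4 EF libraries; a candidate explanation is blood cells in the WT cultures. None of these 16 markers had a mean of 10 CPM in experiment 2, and 0 of the 18 on the list belong to another list. Lyz2, among the most abundant, held 7470, 24100 and 14500 CPM of the library total in the WT libraries. Experiment 2 held no WT library, which can by itself lower the share of genes lower in EF that are expressed there. Of the genes called lower in EF, 37% had a mean of at least 10 CPM in experiment 2, where the markers were near 0, against 64.2% of all genes tested and 76.3% of those called higher. The bound first set for this share (20%) left out the share among all genes and was set aside, since a gene expressed in experiment 2 can also be expressed in blood cells. The test put in its place, after the results were seen, was of collagen and matrix genes, which a loss of blood cells would raise as a share of the RNA. Of these, 6, among them Col3a1 (-4.96), Fbn1 (-3.66) and Sparc (-1.89), were lower in all 4 EF than in all 3 WT, which argues against lost blood cells as the whole cause of the lower genes, while blood cells as the cause for part of them stay open. Whether genotype changed the cells present or the cultures differed for another reason stays open, and no sort is named in the sources used here.

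Library 221 of experiment 1, whose number all titles of experiment 2 carry, had Yap1 at 187 CPM of the library total and was nearer to ha than to EF of experiment 2 in 65% of the 3310 genes called in ha against EF at a log2 fold change of at least 1. The other EF libraries of experiment 1 were nearer to ha in 61.8% (219), 65.8% (229) and 75.2% (225), and the WT libraries in 62.3% to 73.3%. Exchanged EF and ha labels in experiment 2 and a difference between the experiments or flowcells cannot be told apart from a change of the EF cells between them, since the experiments share no sample.

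In CPM of the library total, Xist was at 0.0794 and 0.357 CPM in the EF libraries of experiment 2, 381 and 968 in ha, 125 to 445 in hr, 794 to 1330 in EF of experiment 1, and 2.38, 1.94 and 507 in WT 202, 234 and 237. The Y-linked Ddx3y was at 87.4 and 43.1 CPM in WT 202 and 234 and at 0.134 in WT 237. It was at most 0.0656 in the EF libraries of experiment 1. In experiment 2 the Y-linked Ddx3y and Eif2s3y had 0 counts in every library, and Kdm5d and Uty at most 1. The near absence of Xist in the EF libraries of experiment 2 thus does not make them male by these genes. By these genes WT 202 and 234 are male, while WT 237 and all EF libraries of experiment 1 are female. Sex is thus mixed within WT and partly confounded with genotype in EF against WT. Of the 2887 genes called, 2772 lie on neither sex chromosome. Most genes tested do too, with 503 of 14596 on X, so this count does not limit an effect of sex. Cdkn2a had no count in library EF 221 of experiment 1, and Cdkn2a and Cdkn2b had none in experiment 2, where the neighbouring Mtap had group means of 361 to 452 CPM. The hr libraries differed by first title number: libraries 1-1 and 1-2 against 2-1 and 2-2 had means of 58.8 and 440 TMM-normalised CPM for Ccn1, 8.68 and 68.9 for Ccn2, 302 and 29.1 for Col3a1 and 38.5 and 0.819 for Nptx1. EF of experiment 2 lay between them for each of these genes, at 267, 43.2, 154 and 6.98.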
